A study of Mus musculus with 2 samples.

How the data were processed

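RNA sequencing was done on mouse embryonic fibroblasts (MEFs), connective tissue cells grown in culture from embryos. There was 1 library from wild-type (WT) cells and 1 from cells labelled Ahi1-/-. Per the labels, both were C57BL/6, the embryos were at embryonic day 13.5, the medium was DMEM with 10% serum, and 1 ug of total RNA went into each DNBSEQ library. The targeted part of Ahi1, the number of embryos behind each culture and the passage are not given in the sources used here.

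The authors deposited a table of expected counts for 17260 mRNA genes, with a column headed as read counts for each library. Of the deposited counts, 65.1% of the WT values and 64.4% of the values of the library labelled Ahi1-/- were whole as written, and the rest were fractions of a count. Length-normalised TPM values stand beside them in the same deposited table, per the file headers. A second table deposited by the authors gives FPKM values for 3872 genes. The submitters' processing notes name HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.12 and the mouse genome build mm8, without roles or order. The aligner behind the counts, the annotation, the use of strand and any filter are not given in the sources used here. The column heads read CON and EXP, and were taken as control (WT) and experimental (Ahi1-/-). The files do not spell this out, so every direction below rests on that reading. All 6 columns of values were used and 0 were left out.

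Expected counts were rounded to whole numbers. Library sizes were scaled with the TMM method of edgeR 4.0.16 in R 4.3.3, which gave effective sizes of nearly equal value (log2 ratio, WT over the library labelled Ahi1-/-, -0.01). Scaled counts are given as CPM relative to these effective sizes. The ratio of each gene is the scaled count in the library labelled Ahi1-/- over that in WT. Its exact 95% interval (Clopper-Pearson, on the share of both counts that fell in 1 library) covers counting error only. A gene at 0 in 1 library was set to a floor of 3 counts in that library, or 0.151 CPM in WT and 0.150 CPM in the other, and its ratio is given as "at least". Such a value follows from the floor and is not the limit of the 95% counting interval, which reaches lower. For Gvin1, given as at least 689-fold, that limit is 560-fold. With 1 library per genotype there is no test and no p-value. Genes were counted as higher or lower when they were at least 2-fold apart with at least 50 counts in the higher library. Numbers of list members given as at least 2-fold apart use the same minimum. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for everything after the scaling.

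The genes named in the text follow a rule. It takes Ahi1, then the 12 largest and 12 smallest ratios among genes with at least 200 counts in the higher library and a symbol that is not a predicted gene, clone or accession name. It then takes from each gene list up to 4 members with the largest absolute log2 ratio that met the size rule, or up to 2 with the most counts where none did, and the Y-linked genes. The rule, the 42 gene lists and the first set of alternatives were chosen before the data were examined. Acta2, Thbs1, Ccn2, Col1a1, Col2a1, Acan, Cdkn1a, Mdm2, Trp53, Cdkn2a, Gli1, Ptch1, Ifit1, Ifit2, Isg15 and Igf2 fall outside the rule and were named after their values were seen.

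The lists cover pathways and the cell types that a MEF culture can hold. A member was measured with at least 10 counts summed over both libraries. For each list the text gives the measured members that were higher and lower, the median log2 ratio, and the percentile of that median among 10000 random lists of the same size matched on mean expression in 20 bins. Members at 0 in 1 library entered the median at their bound. A percentile within the outer 2.5% on either side is described as standing apart. It describes these libraries and is not a test of genotype. Medians over a chromosome carry a 95% interval from order statistics, which reflects the spread between genes and not between cultures.

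The reference used for names, chromosomes and neighbours was assembly GRCm38.p6, which is not the build in the submitters' notes, so no coordinates are printed. Of the 17260 gene identifiers, 17210 were found in it. GC content and transcript length came from the longest GENCODE M21 transcript of each gene.

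The calculation was tested on simulated data, drawn for all 17260 genes from the means and library sizes of this comparison with 200 genes changed. All 50 genes simulated at each of log2 3, -3, 1.5 and -1.5 were called. Of 11551 unchanged genes with the minimum count, 1 was called, and the intervals held the true ratio in 95.2% of cases. The simulated counts varied by counting error only, without differences between cultures. These values are therefore not error rates for a comparison of genotypes. Of 200 random lists, 7 fell within the outer 2.5% on either side.

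Alternatives covered the scaling (DESeq2 1.42.0 size factors, total counts, upper quartile, totals without the 20 most abundant genes), the count minimum, the fold threshold, the counting interval as a criterion, the minimum for list members and unmatched random lists. Further alternatives used the deposited TPM or left out groups of genes. Total-count scaling moved every log2 ratio by -0.11 relative to TMM, and ratios are reported relative to TMM. Genes that share sequence with near-identical copies, among them globins, histones, the Ifi200 and H2-Q families, Trim30a, Sp100 and pseudogenes, are uncertain, because expected counts can divide reads between copies. Xist and Tsix were not analysed here, and the values of some list members are not reported here.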

Results

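Messenger RNA was measured in 1 library of wild-type (WT) mouse embryonic fibroblasts and 1 library of fibroblasts labelled Ahi1-/-, both from embryonic day 13.5. Ahi1 encodes a protein of the transition zone at the base of the primary cilium, and mutations of the human gene cause Joubert syndrome. The comparison asks how the transcriptome of fibroblasts labelled Ahi1-/- differs from that of wild-type fibroblasts. The WT library held 19067504 expected counts over 17260 genes and the other library 20820756. Genes at 0 numbered 1218 in WT and 719 in the library labelled Ahi1-/-, and 12950 and 13634 genes reached 10 counts. The 20 most abundant genes took 8.12% and 11.5% of the counts. Each genotype had 1 library and no replicates. The differences therefore have no replicate check, compare these libraries and not the genotypes, and carry intervals for counting error only.

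Ahi1 transcripts were present at nearly equal levels in both libraries. Ahi1 (Entrez gene 52906, on chromosome 10 of assembly GRCm38.p6) had 410 counts in WT and 370 in the library labelled Ahi1-/-. These are 20.7 and 18.5 CPM, and 9.12 and 8.43 TPM. The log2 ratio was -0.16 (95% counting interval -0.37 to 0.05), so the targeted gene did not check the labels. Whether the targeted exons lie inside the counted transcript is not given in the sources used here, and counts per gene cannot show a missing exon. For this reason the second library is called the library labelled Ahi1-/- throughout, and each direction below follows the label and the column heads only.

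Many groups of genes differed between the libraries. The library labelled Ahi1-/- had more transcripts of contractile, matrix, posterior Hox and p53 target genes. It had fewer of proliferation, cartilage, red blood cell, interferon-stimulated and ciliary genes. Among 12075 genes with at least 50 counts in the higher library, 1934 (16.02%) were at least 2-fold higher in the library labelled Ahi1-/-, 1249 (10.34%) were at least 2-fold lower and 8892 lay within 2-fold. At 8-fold or more, 696 were higher and 141 lower, and at 32-fold or more 281 and 44. The interquartile range of the log2 ratios was -0.51 to 0.53 around a median of -0.04. Of the 42 gene lists, the medians of 17 stood apart upward and those of 11 downward.

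**Figure D1:**
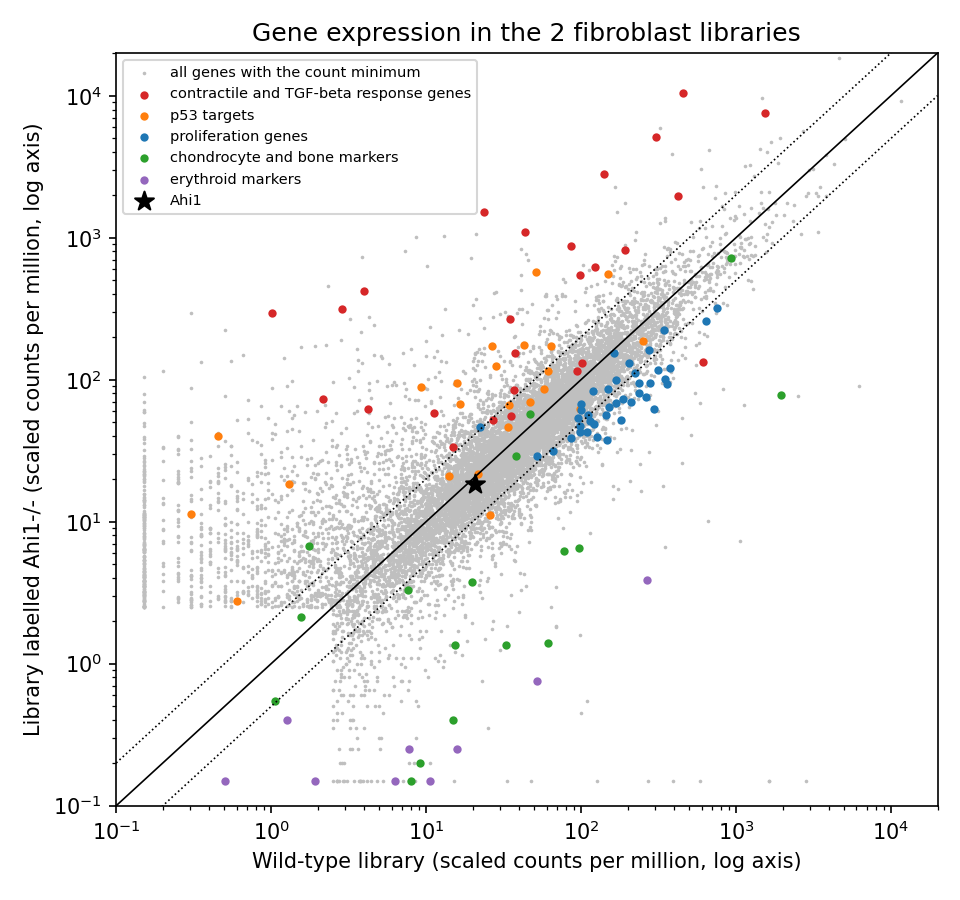
Scaled counts (CPM) of each gene with at least 50 counts in the higher library, WT on the horizontal and the library labelled Ahi1-/- on the vertical log axis, with members of 5 gene lists in colour, equality as a solid line, 2-fold as dotted lines, and genes at 0 drawn at the floor of 3 counts. Ahi1 (star, 20.7 and 18.5 CPM) sits near the line, contractile genes above it, and chondrocyte and erythroid markers mostly below it.

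With genes at 0 set to a floor of 3 counts, the largest upward ratio was that of Fbn2, though counting error and the floor leave the order at the top uncertain. This gene encodes the microfibril protein fibrillin 2 and had 6 counts in WT and 5937 in the library labelled Ahi1-/-, a 981-fold difference (log2 9.94, interval 8.81 to 11.38). Kif1a, a neuronal transport motor, was 572-fold higher (4 and 2308 counts), and Sulf1, a sulfatase that edits heparan sulfate, was 448-fold higher (10 and 4517 counts). Gvin1, an interferon-inducible very large GTPase, had 0 and 2085 counts, at least 689-fold higher. Cdh3, which encodes P-cadherin, was at least 523-fold higher (0 and 1582 counts), and Cck, the gut and brain peptide cholecystokinin, at least 407-fold (0 and 1231 counts). The others of the top 12 had 1 to 3 counts in WT, so their ratios are loosely bounded. Log2 ratios were 9.94 for Jph2 (7.45 to 15.24), 9.20 for Gpc3 (7.34 to 12.24), 9.20 for Il1rl2 (7.34 to 12.24), 8.88 for Gria3 (7.02 to 11.93), 8.86 for Hspb8 (7.31 to 11.14) and 8.62 for Dmd (6.13 to 13.93). Gpc3 encodes the proteoglycan glypican 3 and Dmd encodes dystrophin.

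Among the 12 smallest ratios, globins and other red blood cell genes were the main group. Hbb-b1 was 224-fold lower in the library labelled Ahi1-/- (1998 and 9 counts), Hbb-b2 72.1-fold lower (500 and 7), Hbb-bs 69.6-fold lower (1034 and 15) and Hba-a1 68.4-fold lower (5284 and 78). Counts of single globins are uncertain because the copies are near identical. Slc4a1, the red cell anion exchanger, was 63.2-fold lower (313 and 5 counts). Alas2, the erythroid enzyme of heme synthesis, had 209 and 3 counts (log2 -6.14, interval -8.42 to -4.57). Jag2, a Notch ligand, had 301 and 3 counts (log2 -6.66, -8.95 to -5.10), and C1ql1 was 61.7-fold lower (306 and 5). Ifi202b of the Ifi200 family had 937 and 0 counts, at least 315-fold lower. The pseudogene Rpl34-ps1 (5359 and 0, at least 1802-fold lower), the histone H2ac13 (2184 and 11, 200.3-fold) and Zfp967 (208 and 0 after rounding, at least 70.0-fold) complete the set. Rpl34-ps1 and H2ac13 share sequence with other copies and are uncertain.

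Contractile and extracellular matrix genes were higher as groups in the library labelled Ahi1-/-. Of 26 measured contractile and TGF-beta response genes, 21 were higher and 1 lower, with a median log2 ratio of 2.43, above all 10000 random lists. Cnn1, which encodes the smooth muscle protein calponin 1, had 20 and 5879 counts (291-fold higher). Actg2 was 109-fold higher (57 and 6285), the myosin light chain Myl9 105-fold (79 and 8398) and Tagln 64.2-fold (468 and 30337). At high abundance, Acta2 (smooth muscle actin) was 16.9-fold higher (6025 and 102889 counts), although it lies on chromosome 19, whose genes were mostly lower. Thbs1 had 9024 and 207779 counts (22.8-fold higher). All 27 measured matrix remodelling enzymes and inhibitors lay above 0, 20 of them at least 2-fold, with a median of 1.90 and percentile 100. The stromelysin Mmp3 was 198-fold higher (46 and 9167 counts), Mmp10 at least 93.5-fold (0 and 283), Timp3 61.9-fold (202 and 12613) and Mmp23 34.5-fold (25 and 869). For collagens, 15 of 24 were higher and 3 lower, with a median of 1.69 and percentile 100. The basement membrane chains Col4a1 and Col4a2 were 118-fold and 109-fold higher, Col15a1 12.9-fold and Col12a1 9.99-fold, while Col1a1 was 3.96-fold higher (91910 and 367100 counts). The cartilage collagen Col2a1 was 24.98-fold lower (38926 and 1572 counts).

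Genes that mark position and developmental signalling differed in the same comparison. Of 16 posterior Hox genes, which pattern the limbs and the rear of the trunk, 12 were higher in the library labelled Ahi1-/- and 1 lower, with a median log2 ratio of 4.51 and percentile 100. Hoxd13 had 6 and 756 counts (125-fold higher). Log2 ratios were 8.15 for Hoxd11 (5.66 to 13.46), 7.45 for Hoxa11 (5.90 to 9.73) and 6.18 for Hoxa13 (3.65 to 11.50), each with 1 to 3 counts in WT. The 13 measured anterior Hox genes were mixed, with 3 higher, 5 lower, a median of -0.14 and percentile 27.0. Hoxc5 was 6.70-fold lower, Hoxc4 6.17-fold lower and Hoxd4 3.63-fold lower, while Hoxb5 had 3 and 108 counts (log2 5.16, 3.57 to 7.46). Imprinted genes, which are expressed from 1 parental copy, had 12 of 20 members higher and 2 lower, with a median of 1.92 and percentile 100. Ndn was 290.2-fold higher (6 and 1757 counts), Rtl1 102-fold (14 and 1447) and the fetal growth factor Igf2 17.4-fold (879 and 15471). Snrpn (2 and 186 counts) had a log2 ratio of 6.53 (4.65 to 9.58) and Peg12 (3 and 222) one of 6.20 (4.63 to 8.49).

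Wnt pathway genes were higher in 15 of 34 members and lower in 3, with a median log2 ratio of 1.13 and percentile 99.99. The leading members encode secreted antagonists and a noncanonical ligand. Sfrp1 was 244-fold higher in the library labelled Ahi1-/- (11 and 2703 counts), Dkk3 228-fold (13 and 2991) and Wnt5a 90.4-fold (38 and 3467). Dkk2 had 3 and 262 counts (log2 6.44, 4.87 to 8.72). For the Hedgehog pathway, which signals through the primary cilium, 8 of 24 members were higher and 3 lower, with a median of 0.67 and percentile 99.5. Without the 5 members on chromosomes 8, 17 and 19 the percentile was 96.0, which no longer stood apart. Gpc3 headed the list, and Ccnd1 was 20.7-fold higher (159 and 3314 counts), Hhip at least 27.8-fold (0 and 84) and Osr2 7.50-fold (7 and 53). The list members Gli1 (50 and 13 counts, 3.88-fold lower) and Ptch1 (1676 and 590, 2.87-fold lower) went the other way. They were named after their values were seen.

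Proliferation genes were lower as a group in the library labelled Ahi1-/- while targets of p53 were higher. The cyclin gene Ccnd1, which is on the Hedgehog list and not the proliferation list, was 20.7-fold higher (159 and 3314 counts). Of 40 proliferation genes, 39 lay below 0, 26 were at least 2-fold lower and 1 was higher. The median log2 ratio of -1.24 was below all 10000 random lists. The replication licensing gene Mcm5 was 4.77-fold lower (5889 and 1245 counts), Nusap1 3.91-fold, Mcm7 3.88-fold and the spindle checkpoint kinase Bub1b 3.49-fold. Among 23 p53 targets, 13 were higher and 1 lower, with a median of 1.89 and percentile 100. Eda2r was 88.5-fold higher (9 and 804 counts), Gdf15 37.7-fold (6 and 228), the death gene Pmaip1 14.0-fold (26 and 367) and Ccng1 11.2-fold (1009 and 11420). The cell cycle inhibitor Cdkn1a was 3.70-fold higher (2982 and 11147 counts) and Mdm2 2.70-fold (1261 and 3437). Trp53 itself had 4987 and 3770 counts, 1.33-fold lower. Senescence-associated genes had 10 of 20 members higher and 5 lower, with a median of 0.96 and percentile 100. Cdkn1a and Gdf15 are on both this list and the p53 list. Igfbp5 was 188-fold higher (77 and 14570 counts), Igfbp4 32.4-fold and Hgf 14.5-fold, whereas Cdkn2a, which encodes p16 and p19Arf, was 9.33-fold lower (4735 and 512 counts, log2 -3.22, interval -3.36 to -3.09). The 13 measured replication-dependent histones, several of which share sequence, had 3 higher and 0 lower, with a median of 1.31 at percentile 91.6. It was 2.61 over members with at least 100 counts and 0.78 over those with at least 1. H2bc4 was 7.90-fold and H1f2 6.10-fold higher, while H2ac13, which is not on the list, was 200.3-fold lower.

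Interferon-stimulated genes were lower in the library labelled Ahi1-/-, and the joint list of chemokines and inflammatory cytokines had a higher median with members in both directions. Of 56 interferon-stimulated genes, 47 lay below 0, with 16 at least 2-fold lower and 6 higher. Their median log2 ratio of -0.68 was below all 10000 random lists. Cmpk2 was 8.43-fold lower (1520 and 182 counts), Ifit2 2.68-fold (1736 and 654) and Ifit1 2.10-fold (5268 and 2535), while Isg15 was 1.30-fold lower (3138 and 2433). Ifit1 and Ifit2 lie on chromosome 19. Without the 6 members on chromosomes 8, 17 and 19 the median of the other 50 was -0.63 and its percentile 0. Ifi202b was the lowest member, and Trim30a (23 and 1314 counts, 56.6-fold higher) and Sp100 (25 and 309, 12.3-fold) were higher, all from multi-copy families. Of 28 interferon receptor and nucleic acid sensing genes, 1 was higher and 5 lower. Their median of -0.02, at percentile 69.3, changed sign with upper-quartile scaling (0.04). The bacterial lipopeptide receptor Tlr2 was 5.32-fold lower, Irf5 3.13-fold, the DNA sensor Cgas 2.76-fold and Irf1 2.44-fold. Genes of antigen presentation by MHC class I had 2 of 18 members higher and 3 lower, with a median of -0.42 at percentile 2.40, or 2.91 against unmatched lists. All of them except B2m and Erap1 lie on chromosomes 8 and 17, and the median was -0.09 with chromosome medians subtracted. Tapbp was 2.63-fold, Psmb9 2.34-fold and Psmb10 2.32-fold lower, while H2-Q7, of a multi-copy family, was 12.7-fold higher. Chemokines and cytokines had 17 of 34 members higher and 4 lower, with a median of 1.44 and percentile 100. Cxcl5, which attracts neutrophils, was 50.9-fold higher (415 and 21317 counts), Ccl11 44.1-fold (4 and 178) and Icam1 40.8-fold (7 and 288). Ccl8 had 1 and 90 counts (log2 6.48, 3.96 to 11.80).

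Ciliary genes were modestly lower in the library labelled Ahi1-/-. Of 33 transition zone and Joubert syndrome genes, whose products share the compartment of AHI1, 26 lay below 0, 6 were at least 2-fold lower and 2 higher. The median log2 ratio was -0.57 at percentile 0.030. Tmem107 was 3.04-fold lower (389 and 129 counts) and Tctn2 2.84-fold (515 and 183), while Mks1 was 6.12-fold higher (17 and 105) and Cc2d2a 2.75-fold (182 and 505). Without the 5 members on chromosomes 8, 17 and 19 the median was -0.47 at percentile 0.32. Genes of intraflagellar transport and the BBSome, the cargo machinery of the cilium, had 6 of 33 members lower and 1 higher, with a median of -0.40 at percentile 1.67. Bbs1 (4.54-fold lower, 625 and 139 counts) lies on chromosome 19 and Bbs2 (3.01-fold lower) on chromosome 8, while Bbs9 was 3.26-fold and Ift80 2.94-fold lower on other chromosomes. Leaving out the 4 members on chromosomes 8, 17 and 19 gave a median of -0.37 at percentile 1.48.

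None of 31 cytosolic ribosomal protein genes was 2-fold apart, but 30 lay below 0, with a median log2 ratio of -0.43 at percentile 0.13. Rplp0 had 66837 and 39391 counts (1.71-fold lower) and Rps2, on chromosome 17, 65469 and 41068 (1.61-fold lower). Cholesterol synthesis genes had 1 of 24 higher and 2 lower, with a median of -0.38 at percentile 1.67. Stard4 was 2.26-fold and Pmvk 2.09-fold lower. Lysosome and autophagy genes had 6 of 26 higher and 1 lower, with a median of 0.50 at percentile 99.9. The protease Ctsd was 3.62-fold higher, Hexa 2.62-fold and Wipi1 2.40-fold, and their regulator Tfeb was 2.30-fold lower. Immediate early genes had 7 of 28 higher and 1 lower, with a median of 0.44 at percentile 99.5. Dusp6 was 5.81-fold, Klf4 4.26-fold, Btg2 4.07-fold and Ier5 3.11-fold higher, and Btg2 is also on the p53 list. Glucocorticoid response genes had 2 of 17 higher and 2 lower, with a median of 0.37 at percentile 97.7, but 90.7 without chromosomes 8, 17 and 19 and 91.6 against unmatched lists. Sgk1 was 5.94-fold and Errfi1 3.70-fold higher, and Lcn2 3.22-fold and Mt1 2.90-fold lower.

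The other pathway lists did not stand apart from random lists. Unfolded protein and integrated stress response genes had 3 of 24 higher and 2 lower (median log2 ratio 0.21, percentile 93.3). Dnajb9 and Ddit3 were 2.11-fold and 2.10-fold higher, Atf3 2.54-fold and the chromosome 19 gene Psat1 2.39-fold lower. Heat shock genes had 4 of 15 higher and 0 lower (median 0.14, percentile 81.4, and -0.03 with chromosome medians subtracted), among them Cryab (10.2-fold higher, 107 and 1100 counts), Hspb1 (5.98-fold), Hspa1a (2.24-fold) and Hspb8. Hypoxia and glycolysis genes had 3 of 26 higher and 4 lower, and their median of -0.04 (percentile 46.6) changed sign with upper-quartile scaling (0.01). Adm was 3.85-fold and Car9 3.34-fold higher, Ndrg1 3.01-fold and Pfkp 2.78-fold lower. Among 27 nuclear-encoded oxidative phosphorylation genes, 0 were higher and 1 was lower, the chromosome 19 gene Ndufb8 (2.93-fold), with a median of -0.10 (percentile 42.7). NRF2 and oxidative stress targets had 0 of 23 higher and 2 lower, Gstm1 (2.87-fold) and Tkt (2.09-fold), with a median of -0.18 (percentile 19.9). It was 0.22 without chromosomes 8, 17 and 19. Circadian clock genes had 3 of 19 higher and 3 lower, with a median of -0.27 (percentile 13.2) but a mean of 0.30. Npas2 was 22.2-fold and Rora 12.7-fold higher, Ciart 6.43-fold and Bhlhe41 4.51-fold lower.

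**Figure D2:**
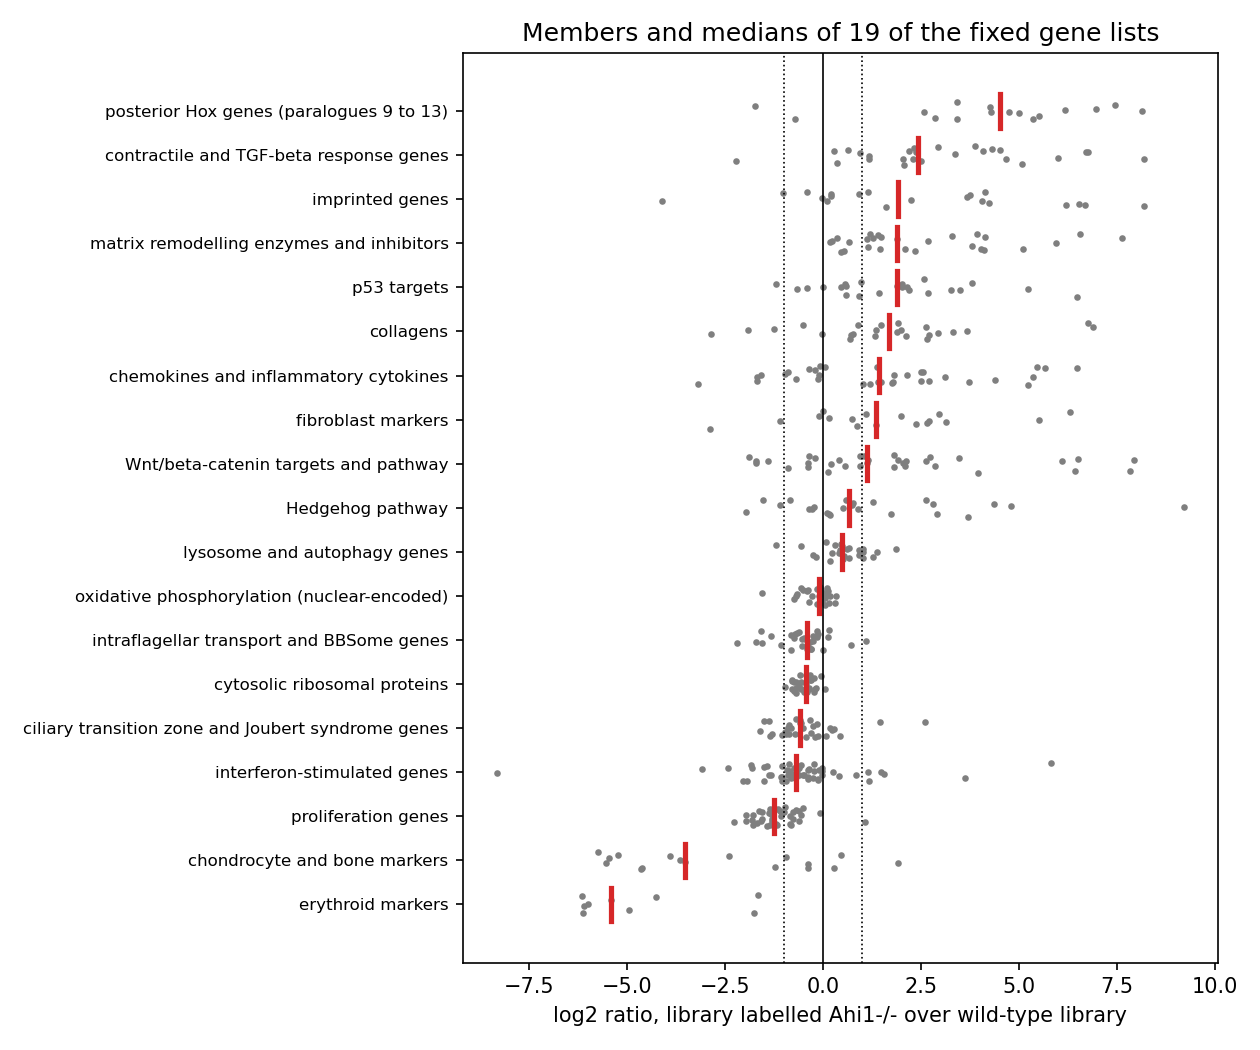
Log2 ratio of each measured member (grey points) of 19 gene lists, the library labelled Ahi1-/- over WT, with the list median as a red bar and 2-fold as dotted lines. Medians run from 4.51 for posterior Hox genes to -5.39 for erythroid markers.

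Markers of cell types that a MEF culture can hold differed in direction. Fibroblast markers had 10 of 17 members higher in the library labelled Ahi1-/- and 2 lower, with a median log2 ratio of 1.36 at percentile 99.99. Thy1 was 79.3-fold higher (258 and 20631 counts), Lum 45.8-fold (71 and 3284), Fbn1 8.88-fold and the receptor Pdgfra 7.81-fold. Mesothelial, smooth muscle and pericyte markers had 4 of 14 higher and 0 lower, with a median of 2.24 and percentile 100. The median was 1.05 over members with at least 100 counts. Lmod1 was 378-fold higher (7 and 2671 counts), Myh11 33.8-fold (43 and 1466) and Cspg4 2.07-fold (1296 and 2707), and Actg2 and Myh11 are also on the contractile list. Chondrocyte and bone markers had 11 of 17 lower and 1 higher, with a median of -3.51 and percentile 0. Cnmd was at least 53.1-fold lower (158 and 0 counts), Matn1 45.9-fold (182 and 4), Col9a1 44.0-fold (1222 and 28), Ibsp 37.3-fold (296 and 8) and Acan, the core proteoglycan of cartilage, 12.5-fold (1537 and 124). All 9 measured erythroid markers lay below 0, with a median of -5.39 and percentile 0. Of these, 6 were at least 2-fold lower with at least 50 counts in WT.

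Neuronal markers had 4 of 8 higher and 0 lower, with a median log2 ratio of 2.22 at percentile 99.3. The median was 4.20 over members with at least 100 counts and 1.57 over those with at least 1. Gap43 was 72.8-fold higher (4 and 294 counts), Map2 18.4-fold (9 and 167) and Tubb3 3.05-fold (428 and 1318), while Stmn2 had 1 and 197 counts (log2 7.61, 5.11 to 12.92). Endothelial markers had 2 of 13 higher and 2 lower, with a median of -1.60 at percentile 0.010. The median was 0.17 over members with at least 100 counts, so its sign rests on sparse genes. Eng was 10.7-fold and Flt1 2.59-fold higher, Plvap 10.3-fold and Egfl7 2.04-fold lower. Macrophage and leukocyte markers had 1 of 18 higher and 3 lower, with a median of -0.61 at percentile 0.78. Lyz1 was 6.99-fold and Cd14 2.36-fold lower, and Lyz2, a near copy of Lyz1, was 3.25-fold higher. Keratinocyte and epithelial markers had 6 of 14 higher and 1 lower (median 1.04, percentile 89.96), with Krt18 4.51-fold and Epcam 3.17-fold higher and Pkp1 12.9-fold lower. Neural progenitor and glial markers had 3 of 11 higher and 2 lower (median 0.57, percentile 72.0), with Ptprz1 49.8-fold higher (15 and 753 counts) and Sox2 8.37-fold lower (83 and 10). Skeletal muscle markers had 2 of 10 higher and 1 lower (median 0.89, percentile 82.4), with Acta1 26.7-fold and Des 14.6-fold higher and Tnnc1 2.02-fold lower. Adipocyte markers had 2 of 9 higher and 3 lower (median -0.11, percentile 32.4), with Fabp4 5.78-fold higher and Plin4 9.38-fold and Pparg 2.72-fold lower. Without chromosomes 8, 17 and 19 the adipocyte median was 0.65. Of 3 measured germ cell and pluripotency markers 0 met the size rule (median 1.31, percentile 70.0), and Nanog had 16 and 25 counts and Ddx4 4 and 11.

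Of the Y-linked genes, Kdm5d and Uty were nearly equal in both libraries, and Ddx3y and Eif2s3y were higher in the library labelled Ahi1-/-. Kdm5d had 539 counts in WT and 473 in the library labelled Ahi1-/-, and Uty 724 and 701. Ddx3y had 20 and 1737 counts (86.1-fold higher) and Eif2s3y 28 and 1129 (40.0-fold higher), while Usp9y had 4 and 0. Why Ddx3y and Eif2s3y were so low in WT while Kdm5d and Uty were not is unexplained and was not tested. The list of 4 measured members had a median log2 ratio of 2.63 at percentile 99.9, and of -0.06 once Usp9y was included, so its direction rests on which members are counted.

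Ratios differed between chromosomes. Of 20 chromosomes, 8 had a median log2 ratio whose interval over genes lay below 0 and 6 one whose interval lay above 0. The lowest medians were those of chromosomes 19, 8 and 17, which were singled out after their values were seen. Chromosome 19 had 430 genes with a median log2 ratio of -0.66 (interval over genes -0.80 to -0.56), with 36.3% at least 2-fold lower and 8.84% higher. Chromosome 8 had 653 genes with a median of -0.40 (-0.46 to -0.32) and 17.2% lower, and chromosome 17 had 603 genes with a median of -0.32 (-0.38 to -0.26) and 12.4% lower. On the other 17 chromosomes medians ran from -0.26 on chromosome 3 (-0.32 to -0.19, 13.3% lower) to 0.28 on chromosome 1, and the share of lower genes from 5.51% to 14.99%. Along chromosome 19, 8 blocks of 53 or 54 neighbouring genes had medians of -0.67, -1.01, -0.70, -0.46, -0.08, -0.90, -1.43 and 0.08. The lowest block runs from Hps1 to Atp5md and the last from Pdcd11 to Csf2ra. Blocks below 0 were 13 of 13 on chromosome 8, 15 of 15 on chromosome 5, 11 of 12 on chromosome 17, 10 of 11 on chromosome 3 and 17 of 19 on chromosome 2.

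**Figure D3:**
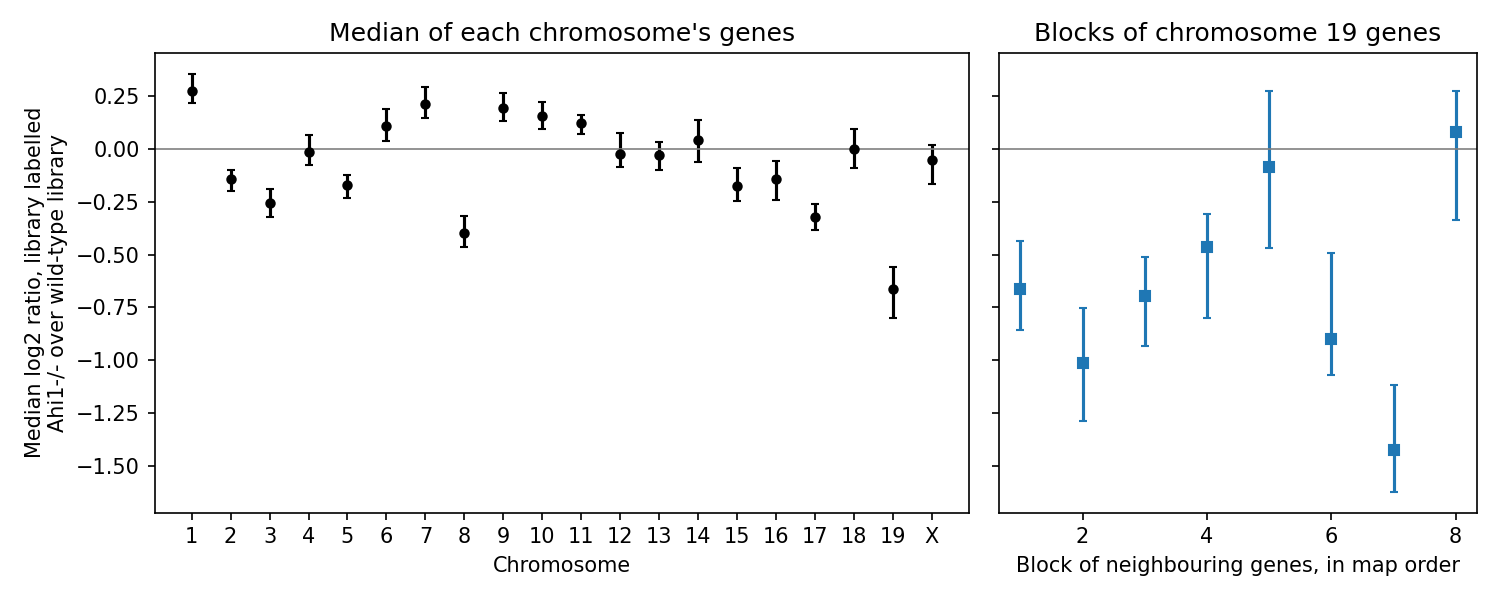
Median log2 ratio of the genes of each chromosome (left) and of blocks of neighbouring genes along chromosome 19 (right), the library labelled Ahi1-/- over WT, with bars for the 95% interval of the median over genes. Chromosome 19 has the lowest median (-0.66), and its blocks run from -1.43 to 0.08.

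Genes next to Ahi1 on chromosome 10 can keep DNA of the strain in which a targeted allele was made, and were looked at for that reason. Of 40 measured genes within 5 Mb in assembly GRCm38.p6, 9 were higher in the library labelled Ahi1-/- and 2 lower, with a median log2 ratio of 0.33 (interval over genes 0.07 to 1.04) at percentile 94.8. They include Sgk1 and Ccn2, a TGF-beta response gene with 868 and 22097 counts (25.2-fold higher). Among genes with at least 50 counts in the higher library, chromosome 10 as a whole had a median of 0.16 (interval over genes 0.10 to 0.22). Of its genes 18.1% were higher and 7.67% lower, against 16.02% and 10.34% over all chromosomes. The percentile was taken against lists from all chromosomes, so it does not single out this locus.

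The FPKM table deposited by the authors lists 3872 genes, 2167 with the higher value in the library labelled Ahi1-/- and 1705 with the lower. Each of the 3872 was at least 2-fold apart by FPKM, so the table holds genes selected on the same libraries. All of them had the same direction by counts, which is therefore no independent check. By scaled counts 3585 were at least 2-fold apart. FPKM ratios were offset by -0.16 on the log2 scale from TPM ratios, because the deposited FPKM were 0.491 of TPM in WT and 0.439 in the other library (medians). Of the 3183 genes counted here as higher or lower, 2998 are in that table. Of the 185 that are not, 177 were higher and 8 lower. Ahi1, which was 1.12-fold lower by scaled counts, is not among these genes selected as at least 2-fold apart.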

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

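The alternatives with deposited TPM, without chromosomes 8, 17 and 19, with chromosome medians subtracted, without predicted genes and without other cell type lists were chosen after seeing the data. Of 404 recomputed list medians, 399 stayed within the interval of the list, 3 moved beyond it in the same direction and 2 of lists that stood apart changed sign. These were endothelial markers, at 0.17 with members of at least 100 counts, and the Y-linked list, at -0.0595 with members of at least 1 count. Sparse members left or joined these lists, which shows the cause. The minimum for members also moved the medians of neuronal markers (1.57 to 4.20 against 2.22), mesothelial, smooth muscle and pericyte markers (1.05 against 2.24), histones (0.78 to 2.61 against 1.31) and imprinted genes (1.38 against 1.92). Over all alternatives the posterior Hox median reached 5.18 against 4.51, and the erythroid median -6.04 against -5.39. Of 940 recomputed log2 ratios of single genes, 883 stayed within their counting interval, 57 moved beyond it, and of genes at least 2-fold apart 0 changed sign. Most of these values came from scalings, each of which moved every log2 ratio by the same amount, about 0.11 at most. For them the absence of sign changes was fixed in advance. The Ahi1 log2 ratio ran from -0.28 with total counts to -0.11 with upper-quartile scaling. The count of higher genes became 1266 with a minimum of 200 counts, 3111 with no minimum and 1078 at 4-fold. That of lower genes became 2063 with no minimum, 2606 at 1.5-fold and 299 at 4-fold. These settings admit or exclude genes by construction. Every other alternative kept both counts within 1.5 times of 1934 and 1249, among them 1774 and 1537 with total counts, 2004 and 1140 with upper-quartile scaling and 1608 and 859 with the counting interval wholly beyond 2-fold. Of 82 recomputed list percentiles, 75 kept their side of the outer 2.5%. Against unmatched lists histones (99.9), keratinocyte (99.7) and skeletal muscle markers (98.0) joined, and MHC class I and glucocorticoid genes left. Without chromosomes 8, 17 and 19, Hedgehog (96.0) and glucocorticoid genes (90.7) left, and too few MHC class I members remained for a value. The cause of these shifts was not tested. No paired analysis was possible because each genotype has 1 library, and for the same reason leaving out a replicate was not run. Depth limits genes with few counts, such as Jph2 or Hoxd11 with 1 count in WT, whose intervals span several log2 units.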

Other observations

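Among the tests in this part, those on the step between blocks of chromosome 19, both tests on Ahi1 and the one on Cdkn2a were chosen only after the result was seen, as were the genes named here and in the next paragraph. At 0 counts in WT and at least 200 in the library labelled Ahi1-/- were 23 genes, 3 of them predicted genes or pseudogenes. Tnmd, the tendon and ligament protein tenomodulin, had 581 counts (at least 192-fold higher), Hand2, a limb and heart transcription factor, 383 (at least 127-fold) and Msx2, a limb and skull transcription factor, 229 (at least 75.7-fold). Itga8, an integrin chain of mesenchyme, had 540 counts (at least 178-fold), the growth factor Pdgfd 436 (at least 144-fold), the oxysterol hydroxylase Cyp7b1 771 (at least 255-fold) and the guanylate-binding protein Gbp2b, of a multi-copy family, 795 (at least 263-fold). Among those known from neurons, Bhlhe22 had 223 counts (at least 73.7-fold), Brinp1 220 (at least 72.7-fold) and Nptx2 216 (at least 71.4-fold).

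In the opposite direction 8 genes had at least 200 counts in WT and 0 in the library labelled Ahi1-/-, and 6 of them are predicted genes or pseudogenes. Gm52701, Gm52236 and Gm52796 had 55911, 32449 and 32188 counts in WT. All 1027 predicted genes, clone names and pseudogenes took 3.36% of the counts in WT and 0.880% in the other library. Ifi202b, known for low expression in C57BL/6, the strain labelled for both cultures, had 937 and 0 counts.

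For the lower ratio of chromosome 19 genes, with smaller shifts on 8, 17 and other chromosomes, gene properties are argued against as the whole cause, because medians lay -0.668 (19), -0.410 (8) and -0.340 (17) away from the median of 1000 random lists matched on GC content, transcript length and expression, each below all 1000. On a dosage difference of the whole chromosome the sign of the blocks could not decide. Medians were negative in 7 of 8 blocks, which met neither bound set before the test. The last adjacent blocks had medians of -1.43 (interval over genes -1.62 to -1.12) and 0.08 (-0.34 to 0.27). Intervals this far apart argue against a uniform shift as the only cause in these libraries. As part of the cause it cannot be told apart from others. A dosage difference of segments, such as extra copies in the WT culture or losses in the other, remains a candidate explanation, since the largest step between adjacent blocks (1.51) exceeded all 198 steps on other autosomes (at most 0.69, on chromosome 7). It is a hypothesis found on these data, copy number was not measured, and with 1 library each a culture effect and the genotype stay confounded.

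Ahi1 was nearly equal in both libraries. Exchanged columns would not account for this, because a lost transcript would then be at least 2-fold higher there, and the upper bound of the log2 ratio was 0.0453. An exchange is not excluded if the allele leaves the transcript in place. A targeted allele that still makes a transcript, for instance with a short deletion, could give the log2 ratio of -0.16, and it cannot be told apart from a wrong label or an untargeted culture because no counts per exon were used. The direction of every other difference rests on the label for that reason.

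Targets of p53 were higher in the library labelled Ahi1-/- while proliferation genes and Cdkn2a were lower. With chromosome medians subtracted the list median was 1.75 instead of 1.89. That it stayed high was fixed in advance, because the highest chromosome median was 0.28. Shifts of whole chromosomes are thus too small to be the whole cause. Gene properties are argued against as the cause, since the list median exceeded the median of 1000 matched lists by 1.98. The highest matched list was at 0.62. A difference in p53 function between the cultures is a possible explanation, because cultured MEFs that escape senescence often lose p53 or Arf function, and high Cdkn2a with low p53 target expression in WT (Cdkn2a log2 ratio -3.22) would go with a loss of p53 in that culture. An effect of the Ahi1 genotype or of passage cannot be told apart from it with 1 library per genotype. Variants of Trp53 were not analysed here.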
